A study of Schizosaccharomyces pombe with 3 samples.

How the data were processed

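Small RNA was measured in wild type, a dcr1 deletion and dcr1-deltaC33, with 1 library for each of the 3 strains. Per the labels' protocols, total RNA was taken from cells at an optical density of 0.5 by hot phenol, RNA of 17 to 30 nt was cut from a gel, linkers were ligated, and the barcoded libraries were sequenced on an Illumina Genome Analyzer. Per the file headers and the values, each deposited file lists every distinct sequence once with its raw counts of reads, which the authors did not normalize. The tool that trimmed linkers, any filter, and the aligner and genome build of the authors are not given in the sources used here. Groups were taken from the labels, and 3 comparisons were made: each mutant over wild type, and dcr1-deltaC33 over the deletion.

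Depths were 469747, 222750 and 303536 reads for wild type, the deletion and dcr1-deltaC33, so 3 counts, taken as the floor, stand for 18.5, 33.8 and 24.0 RPM (reads scaled to the matched reads of each library). Every sequence was matched without mismatch to both strands of the assembly ASM294v3 of S. pombe, which may differ from the build the authors used. Reads that did not match were left out. A sequence with matches in several RNA classes went to the first of rRNA, tRNA, snRNA, snoRNA, other ncRNA, centromere, mating type region, subtelomere, retrotransposon, mitochondrial, mRNA sense, mRNA antisense, and intergenic or lncRNA. The annotation used does not mark the centromeric repeats, so each centromere was taken as the chromosome's longest stretch without a protein-coding gene. Its core was taken as the stretch between the innermost inverted repeats of at least 1500 bp and 98% identity in blastn 2.17.0. A subtelomere was the outermost 50 kb at each end of chromosomes 1 and 2, and the mating type region the stretch between rpp202 and emc3. A random sequence of 14 nt would match the genome by chance in 8.95% of cases, one of 17 nt in 0.146%.

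Shares have exact Clopper-Pearson intervals, counts exact Poisson intervals, and ratios exact conditional binomial intervals, all at 95% and for counting error only. Where a mutant had 0 reads, a loss of at least some fold is the lower limit of the ratio's interval. No p-value was computed, since each group has 1 library. Features are annotated genes, sense and antisense apart, with at least 20 single-match reads over the libraries. Their log2 ratios use a pseudocount of 0.5, and a feature counts as lower or higher where its interval excludes 1. The text names the regions, dcr1, the 10 lowest and 10 highest features with at least 50 reads and an interval that excludes 1 for each mutant over wild type, the 5 lowest and 5 highest for dcr1-deltaC33 over the deletion, and 2 to 4 members with most reads per list where reads allow. There were 10 lists: RNAi and heterochromatin factors, meiotic genes, stress and heat shock genes, glycolysis and translation genes, ribosomal proteins, histones, Tf2 retrotransposons, stable noncoding RNAs, cytoskeleton, and centromere neighbours. A list's median was set against 10000 random lists matched on read number, as a description of these libraries.

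The matching was tested on 2000 planted genome sequences, of which 2000 were found at their place, and on 2000 random sequences of 22 nt, of which 0 matched. The feature test was tested on Poisson counts simulated for the 439 features, 200 of them changed, as many up as down. The simulation held no spread between libraries beyond counting error and no shared shift of mRNAs, so its rates hold for counting error only. For the deletion over wild type the test recovered 46.6% of 2-fold and 83.8% of 4-fold changes, for dcr1-deltaC33 over wild type 52.6% and 89.3%, and for dcr1-deltaC33 over the deletion 44.1% and 86.1%. Between 2.84% and 3.55% of unchanged features were called. Alternatives covered the denominator, read length, first base, distinct sequences, sequences read once, class order, multiple matches, 1 mismatch (bwa 0.7.19-r1273), pseudocount, read minimum and scaling to the median ratio of protein-coding genes. Reads without tRNA trailers, and features, classes and regions from reads of 17 to 30 nt, were added after the data were seen. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.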

Results

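Small RNAs of 3 strains of the fission yeast Schizosaccharomyces pombe were sequenced, with 1 library per strain. The strains were wild type, a deletion of dcr1 (the gene for Dicer, the ribonuclease that cuts double-stranded RNA into small interfering RNAs), and dcr1-deltaC33, whose Dicer lacks its last 33 amino acids. The libraries held 469747 reads for wild type, 222750 for the dcr1 deletion and 303536 for dcr1-deltaC33, between 14 and 35 nt long. Of these, 162301 (34.6%), 88783 (39.9%) and 125160 (41.2%) matched the reference genome without a mismatch, and values are in RPM, which scales each library to the same number of these matched reads. No difference has a replicate check. The 95% intervals are exact and cover counting error only, since PCR reads without molecular identifiers are not independent molecules. A test on reads therefore compares these libraries, not the strains.

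The targeted gene came first. The coding sequence of dcr1 (SPCC188.13C, chromosome 3, 1504949 to 1510557, minus strand) gave 1 sense read in wild type, 0 reads in the deletion, and 1 sense and 2 antisense reads in dcr1-deltaC33. No library had a read in the last 33 codons. The 0 reads in the deletion allow up to 41.5 RPM, above the 6.16 RPM of wild type, so dcr1 was too shallow to check the labels. Linker reads, in which the 5′ linker and its barcode had no insert of their own, carried the labelled barcode in 99.8% of wild-type, 92.0% of deletion and 99.9% of dcr1-deltaC33 cases.

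The first comparison asked which small RNAs were lost without Dicer. Centromeric small RNAs, which in wild type come from the repeats on either side of each centromere's core and guide heterochromatin there, almost disappeared. They made up 9.25% of matched reads in wild type (15014 reads, 95% interval 9.11% to 9.39%) and 0.128% in the dcr1 deletion (114 reads, 0.106% to 0.154%), 72.04-fold less (59.9 to 87.4). Small RNAs of tlh1 and tlh2, subtelomeric genes for RecQ-type helicases that share sequence with the centromeric repeats, fell from 179 reads to 0, at least 26.3-fold, and 51.4% of those 179 wild-type reads also matched the centromeres. All reads of the outermost 50 kb of chromosomes 1 and 2, which include the 179 of tlh1 and tlh2, fell 9.32-fold (6.07 to 15.1), from 375 to 22 reads, and 18.2-fold from reads of 17 to 30 nt. Of the 375 wild-type reads 30.7% also matched the centromeres. Single-match subtelomeric reads, 11 in wild type, were too few for an interval that excluded 1 in either mutant.

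In wild type the centromeric reads lay in separate blocks. Centromeres 1, 2 and 3 (chromosome 1, 3751730 to 3790923; chromosome 2, 1596745 to 1648231; chromosome 3, 1064444 to 1142615, assembly ASM294v3) held 4, 4 and 11 blocks with at least 100 RPM per 500 bp. These blocks took 98.2%, 97.3% and 97.98% of each centromere's reads on 35.7%, 25.2% and 46.7% of its length. Wild-type reads came to 0.391 RPM per kb in the central cores, on which the kinetochore is built, 782 in the flanks outside the arms and 184 in the inverted repeat arms around the cores. The arms of centromere 1 gave 333 and those of centromeres 2 and 3 gave 0.497 and 9.81, but the arms differed in length (left arms of 12834, 4136 and 6585 bp). Those of centromere 1 reached far enough to hold the blocks at 3761501 to 3764500 and 3777501 to 3781000. The contrast between centromeres may thus come from where the arms were set to end. Reads with a single match numbered 68, 270 and 1471 in centromeres 1, 2 and 3 of wild type, and 1, 0 and 34 in the deletion. For centromere 2 this was at least 39.8-fold less, and for centromere 3 it was 23.7-fold less (16.9 to 34.3), or 67.9-fold less (37.8 to 136.3) without reads that begin right after a tRNA gene. The mating type region (chromosome 2, 2128468 to 2138318), another heterochromatic domain, gave 2 reads in wild type and 1 in each mutant, so no difference was detectable there at this depth.

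**Figure D1:**
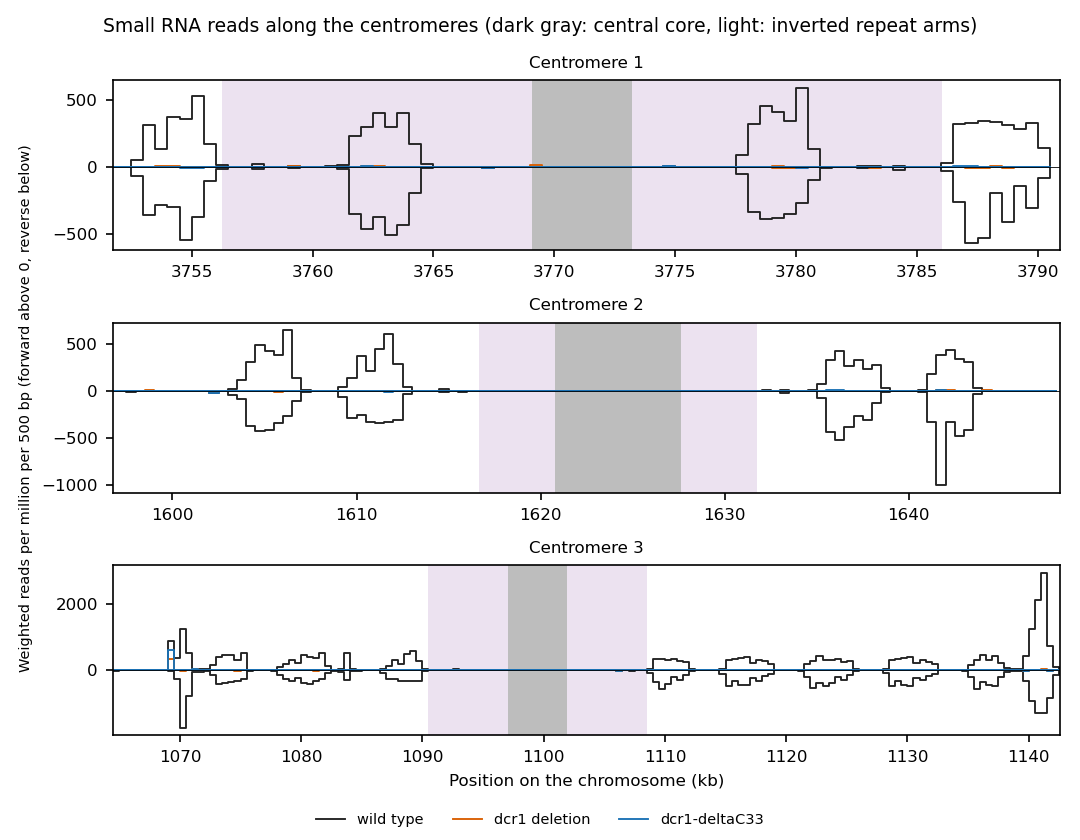
RPM in 500 bp bins along each centromere, each match weighted by 1 over its read's number of matches, with forward reads above 0 and reverse reads below, for the 3 libraries. Dark gray marks the central core and light shading the inverted repeat arms. The wild-type line rises in blocks on both strands outside the cores, up to 4252.9 RPM in 1 bin of centromere 3 (both strands added), and the lines of both mutants stay near 0 except beside the tRNA gene at 1069166 on chromosome 3.

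The wild-type centromeric reads differed from mRNA fragments in size and first base. Among those of 17 to 30 nt, 42.2% (41.3% to 43.0%) were 22 or 23 nt long and 65.7% (64.9% to 66.6%) began with U, against 13.8% and 29.3% among mRNA sense reads of the same library. They lay on both strands, with 59.0% (56.7% to 61.3%) of 1809 single-match reads forward, 32.4%, 31.5% and 65.3% in centromeres 1, 2 and 3. Of the centromeric reads left in the deletion and in dcr1-deltaC33 37.6% (27.8% to 48.3%) and 36.2% (28.2% to 44.8%) were 22 or 23 nt long. Those in the deletion began with U in 40.9% of cases (30.8% to 51.5%), in 18.8% with 1 match, in 7.41% of sequences read at least 2 times, and in 55.1% (42.6% to 67.1%) without tRNA trailers, against 66.3% (65.5% to 67.2%) of wild-type reads without trailers. In the deletion 94.3% (80.8% to 99.3%) of 35 single-match reads were forward, or 83.3% (51.6% to 97.9%) of 12 without tRNA trailers. Of all 114 centromeric reads of the deletion, 31 began at the first base after a tRNA gene on its strand, 29 of them after SPCTRNALEU.11 (a leucine tRNA gene at the edge of centromere 3, chromosome 3, 1069166 to 1069244, singled out after its values were seen). Without such tRNA trailers the loss was 97.7-fold (78.8 to 122.7). Linker reads of the deletion library carried the wild-type barcode in 7.92% of cases (7.19% to 8.70%). With the centromeres placed before rRNA and tRNA in the order of classes, their tRNA genes entered the count and the ratio was 1.25-fold. The other 12 alternatives gave 31.5-fold to 117-fold.

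**Figure D2:**
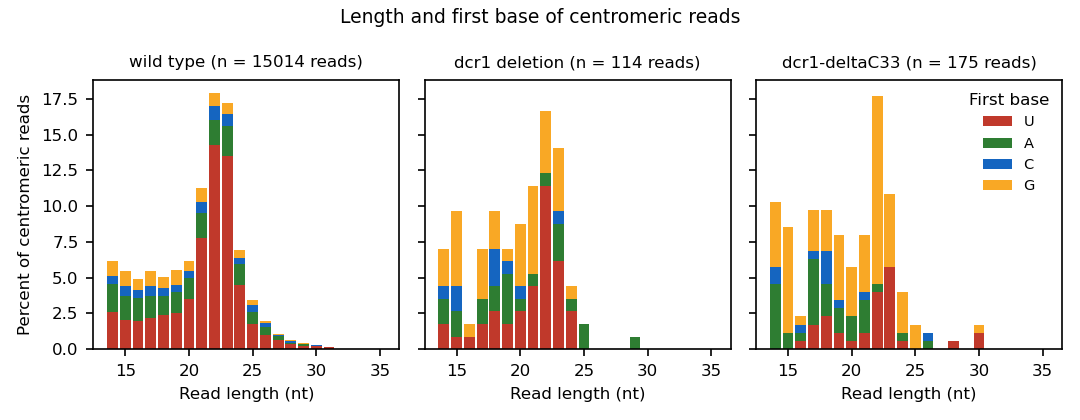
Percent of all centromeric reads at each length in nt, stacked by first base, in the 3 libraries (15014, 114 and 175 reads). In wild type the highest bars stand at 22 and 23 nt and are mostly U, while the mutants' bars rest on few reads.

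Outside heterochromatin, fragments of mRNA were fewer in the deletion and those of many tRNAs more frequent. Nuclear mRNA sense reads were 0.634 of wild type (0.613 to 0.655), tRNA reads were 1.25-fold and rRNA reads 1.08-fold higher (2.48-fold for rRNA counted as distinct sequences), and the median log2 ratio of 206 nuclear protein-coding genes was -0.49. These are shares of all matched reads, so the loss of centromeric reads, 9.25% in wild type, by itself raised other shares in both mutants. The 1.08-fold rise of rRNA reads cannot be told apart from that. Of 439 features with at least 20 single-match reads over the libraries, 47 were lower and 52 higher with an interval that excluded 1. Scaled to the median ratio of protein-coding genes, 21 were lower and 88 higher. The strongest losses were centromeric lncRNAs near the ends of centromeres 2 and 3. SPNCRNA.7235 (chromosome 3, 1140813 to 1141069) fell from 280 sense and 112 antisense reads to 0, at least 41.2-fold and 16.3-fold, and SPNCRNA.5276 from 82 reads to 0, at least 11.9-fold. SPNCRNA.7236 (chromosome 3, 1141320 to 1142247) fell from 320 sense reads to 2, a ratio of 0.0114 (0.00138 to 0.0416), and from 226 antisense reads to 2, a ratio of 0.0162 (0.00195 to 0.0591). With matches weighted by 1 over their number its antisense log2 ratio was -1.88.

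Among mRNAs, rpp202 (a ribosomal stalk protein, the gene beside the mating type region) fell by 2.61 on the log2 scale (log2 ratio -1.99 after median-ratio scaling and -1.89 as distinct sequences). SPAC27E2.11C, a gene that overlaps the noncoding RNA prl53, fell by 1.57, or 0.94 after median-ratio scaling (log2 ratio -2.55 from reads of 17 to 30 nt), but its interval included 1 as distinct sequences (-0.36). The gene cut6, for acetyl-CoA carboxylase, fell by 1.70, but its interval included 1 after median-ratio scaling, where its log2 ratio was -1.07. Reads antisense to cut23 (an anaphase-promoting complex subunit), which are sense for SPNCRNA.2584, fell by 1.86, or 1.23 after median-ratio scaling. All of these cut23 reads were 14 to 16 nt long, and 918, 188 and 256 longer reads that hold the most-read sequence matched nowhere in the genome. The features that rose most were mitochondrial transcripts and nuclear tRNAs. Mitochondrial trnR(ucu) rose from 124 to 224 reads (log2 ratio 1.72), trnS(uga) by 1.63, trnC(gca) by 1.24 and trnS(gcu) by 0.99 in log2 ratio. The nuclear tRNAs SPBTRNAARG.04, SPATRNAPRO.01, SPBTRNATYR.04 and SPBTRNAHIS.02 had log2 ratios of 1.495, 1.42, 1.20 and 1.20. Counted as distinct sequences trnR(ucu), trnS(uga) and trnC(gca) had 0.72, 0.82 and 0.52, and the intervals of SPATRNAPRO.01 (0.42) and SPBTRNAHIS.02 (0.21) included 1, while from reads of 17 to 30 nt these tRNAs had 2.04 and 2.00. The mitochondrial genes atp6 (an ATP synthase subunit) and rnpB (the RNase P RNA) both reached 1.01. In all, 25 of 38 mitochondrial and 16 of 32 nuclear tRNA features were higher in sense. The mitochondrial class, which leaves out tRNA and rRNA genes, was not higher as a whole, at 0.953 of wild type (0.881 to 1.03).

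Gene lists fixed before the data were examined moved by different amounts. Of 67 measured ribosomal protein genes 6 fell and 1 rose, with a pooled ratio of 0.638 (0.579 to 0.702) that became 0.984 after median-ratio scaling, and rpl8 gave 51 reads in wild type, 12 in the deletion and 24 in dcr1-deltaC33. The list's median stood at percentile 1.6 of 10000 random lists matched on read number. Of 12 measured glycolysis and translation genes 2 fell, with a pooled ratio of 0.723 (0.633 to 0.824) that turned to 1.12 after that scaling and percentile 73.8. Reads of tdh1 (glyceraldehyde-3-phosphate dehydrogenase) numbered 179, 67 and 89, and those of fba1 (aldolase) 73, 29 and 36. Of 6 measured stress and heat shock genes, sks2 and ssa2, both for Hsp70-type chaperones, fell, with a pooled ratio of 0.480 (0.358 to 0.636), 0.741 (0.552 to 0.981) after scaling, and percentile 10.97. Among 7 measured stable noncoding RNAs prl53 fell (151 and 36 reads) and srp7, the signal recognition particle RNA, rose 1.41-fold (1.20 to 1.66), with the list at percentile 70.9. After median-ratio scaling, 2 ribosomal protein genes were lower and 2 higher, and 0 glycolysis and translation genes were lower and 1 higher. Of the stress and heat shock genes 0 were lower and 0 higher, and of the stable noncoding RNAs 1 was lower and 2 were higher.

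The second comparison asked whether Dicer without its last 33 residues, the part that the study connects with the protein's place in the nucleus, still gave centromeric small RNAs. It left few of them. Centromeric reads were 0.140% of matched reads in dcr1-deltaC33 (175 reads, 0.120% to 0.162%), 66.2-fold less than in wild type (57.0 to 77.2). Single-match reads of centromeres 1, 2 and 3 numbered 0, 0 and 79, at least 56.1-fold less for centromere 2 and 14.4-fold less (11.4 to 18.2) for centromere 3, or 61.9-fold less (38.5 to 106.6) without tRNA trailers. Reads of tlh1 and tlh2 fell to 0, at least 37.0-fold, and subtelomeric reads, which in wild type include those of tlh1 and tlh2, fell 5.16-fold (3.89 to 6.97) to 56 reads. Of those 56 reads 45 matched the right end of chromosome 1, and from reads of 17 to 30 nt the subtelomeric counts were 219 in wild type and 14 in dcr1-deltaC33, 12.9-fold less.

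The remaining centromeric reads of dcr1-deltaC33 began with U in 23.9% of cases (17.1% to 31.9%), and 93.7% (85.8% to 97.9%) of 79 single-match reads were forward. Without tRNA trailers these shares were 44.3% and, of 17 reads, 70.6% (44.0% to 89.7%), and with 1 match 7.89% began with U. Reads that began right after a tRNA gene made up 86 of the 175 (49.1%), 80 of them after SPCTRNALEU.11, and the loss without them was 128-fold (104 to 160). The most-read of these in dcr1-deltaC33, GTACTGAAAATTTTTGGAGTTT, had 27 reads in wild type, 5 in the deletion and 21 in dcr1-deltaC33. With the centromeres first in the class order the ratio was 1.40-fold, and the other 12 alternatives gave 30.5-fold to 167-fold.

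Other RNA classes of dcr1-deltaC33 also differed from wild type. Nuclear mRNA sense reads were 0.642 of wild type (0.624 to 0.661), with a median log2 ratio of -0.74 over the 206 genes. Reads of rRNA were 1.32-fold (3.28-fold as distinct sequences) and those of spliceosomal snRNAs 1.76-fold (1.45 to 2.14) higher. Of 439 features 95 were lower and 39 higher, and 20 and 101 after median-ratio scaling. The centromeric lncRNAs led again: SPNCRNA.7235 fell to 2 sense reads, a ratio of 0.00926 (0.00112 to 0.0338). Its antisense reads fell to 0, with an interval of the ratio that reached up to 0.0434. SPNCRNA.7236 fell to 1 sense read, a ratio of 0.00405 (0.000102 to 0.0227), and 6 antisense reads (log2 ratio -4.75, and -1.38 with weighted matches), and SPNCRNA.5276 to 0, at least 16.8-fold. The nuclear tRNA SPBTRNAASN.04 fell from 60 to 8 reads (log2 ratio -2.46, -1.70 after median-ratio scaling, -1.31 as distinct sequences and -0.59 with weighted matches). The gene eca39, for a branched-chain aminotransferase, fell by 2.11 (1.35 after scaling) and rpp202 by 1.81 (1.05). The 5S rRNA genes SPRRNA.11 and SPRRNA.18 fell by 1.71 and 1.59 (0.95 and 0.83), but their intervals included 1 as distinct sequences (-0.86 and -0.38). Of the SPRRNA.18 reads 65.9% were 14 to 16 nt long, and from reads of 17 to 30 nt its log2 ratio was -0.90.

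The snRNAs snu1 (U1) and snu2 (U2) rose from 12 to 36 and from 35 to 76 reads, log2 ratios of 1.92 and 1.48. Nearly the same reads gave the rise of SPNCRNA.5934 antisense (1.89), which overlaps snu1. The threonine tRNA genes SPATRNATHR.03 and SPATRNATHR.04 rose by 1.29 and 1.06 in log2 ratio, together with the antisense reads of the lncRNAs that overlap them, SPNCRNA.3283 (1.26) and SPNCRNA.3411 (1.09). Reads of hsp16, a small heat shock protein, rose from 16 to 29 (log2 ratio 1.21). From reads of 17 to 30 nt its log2 ratio was 0.92, with an interval that included 1. Mitochondrial rns, the small subunit rRNA, rose by 1.16 and antisense reads of cox1 (cytochrome c oxidase) by 0.95.

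Of the 67 ribosomal protein genes 14 fell and 0 rose (pooled ratio 0.592, 0.542 to 0.646, percentile 5.44), and after median-ratio scaling the pooled ratio was 1.002. With that scaling 3 of the 67 were lower and 5 higher. Of 12 glycolysis and translation genes 8 fell, among them pdc101 (pyruvate decarboxylase; 95 and 31 reads) and pgk1 (phosphoglycerate kinase; 77 and 29 reads), with a pooled ratio of 0.593 (0.523 to 0.671), 1.004 after scaling, and percentile 22.2. None of these falls was called after scaling, where 0 of the 12 were lower and 1 was higher. Of 6 stress genes sks2 and ssa2 fell and hsp16 rose, with a pooled ratio of 0.783 (0.633 to 0.967) that turned to 1.33 after scaling, and percentile 98.6. Scaled, 0 of the 6 were lower and 1 was higher. Among 7 stable noncoding RNAs 2 fell, srp7 (0.658, 0.545 to 0.792) and prl53 (0.447, 0.319 to 0.616), and 3 rose, all snRNAs, with snu4 (U4) at 1.46 (1.097 to 1.95) and the list at percentile 96.1. After median-ratio scaling 0 of the 7 were lower and 3 were higher, so neither fall was called. Histone genes had no member with 20 reads; their pooled reads numbered 73, 22 and 29, ratios of 0.551 (0.326 to 0.898) and 0.515 (0.323 to 0.802) for the deletion and dcr1-deltaC33, and both intervals included 1 after median-ratio scaling.

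**Figure D3:**
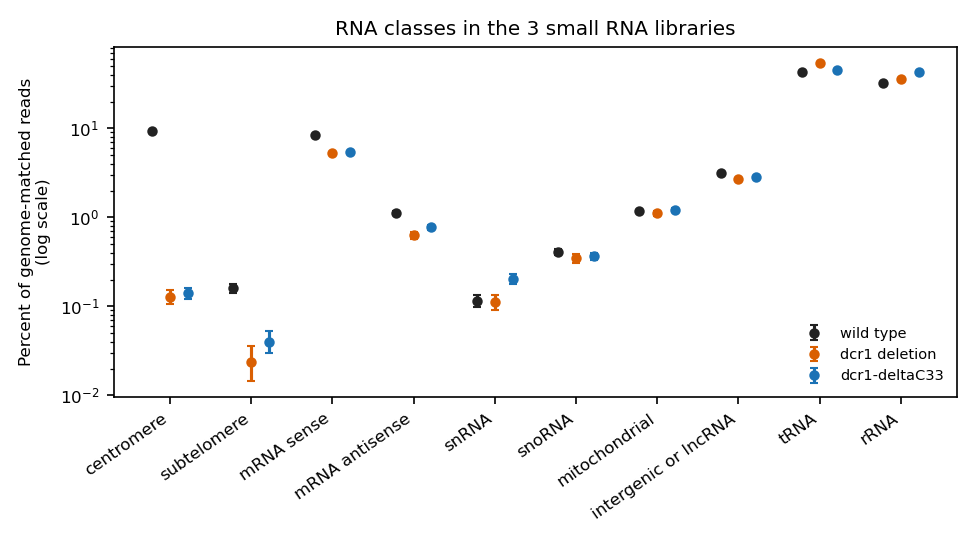
Percent of genome-matched reads per RNA class on a log scale, with exact 95% intervals for counting error, in the 3 libraries. Centromeric and subtelomeric reads of both mutants lie below wild type, and mRNA reads are lower by less.

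The third comparison set the mutants side by side. No difference in centromeric reads was detectable between dcr1-deltaC33 and the deletion (ratio 1.09, 0.855 to 1.39), and without tRNA trailers the ratio was 0.761 (0.558 to 1.04). Carry-over was not subtracted, and linker reads held the wild-type barcode in 7.92% of cases in the deletion and 0.0439% in dcr1-deltaC33. Wild-type reads in the deletion library could therefore hide a higher level in dcr1-deltaC33. Single-match reads of centromere 3 were 1.65-fold higher in dcr1-deltaC33 (1.09 to 2.54), but most of them were tRNA trailers, which were 1.97-fold higher (1.29 to 3.07), and without these the ratio for centromere 3 was 1.096 (0.484 to 2.59). The centromeric ratio depended on how reads were counted: it was 0.606 (0.445 to 0.824) as distinct sequences, 0.894 (0.879 to 0.910) with the centromeres first in the class order and 2.43 (1.63 to 3.70) with sequences read at least 2 times. Subtelomeric reads were 1.81-fold higher (1.08 to 3.11), and 1.41-fold with an interval that included 1 from reads of 17 to 30 nt.

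The snRNAs snu1, snu2 and snu4 were higher in dcr1-deltaC33 than in the deletion, with log2 ratios of 1.17 and 1.27 for snu1 and snu2 and a ratio of 1.67 (1.17 to 2.42) for snu4. Antisense cox1 (log2 ratio 2.23), hsp16 (1.30) and the small nucleolar RNA snoZ8 (1.14) were higher too, though from reads of 17 to 30 nt the intervals of hsp16 and snoZ8 included 1, and so did those of snu1 (0.81), hsp16 (1.12) and snoZ8 (0.07) as distinct sequences. The tRNAs SPBTRNAASN.04, SPBTRNAGLY.09 and SPATRNAPRO.01 (log2 ratios -2.78, -1.43 and -1.14) and the mitochondrial trnR(ucu) and trnS(uga) (-1.56 and -1.33) were lower. As distinct sequences SPATRNAPRO.01 turned to 0.034, SPBTRNAGLY.09 (-0.56) had an interval that included 1, and SPBTRNAASN.04 and trnR(ucu) had -1.60 and -0.77, while with weighted matches SPBTRNAASN.04 had -0.66. Of the SPBTRNAGLY.09 reads 86.6% were 14 to 16 nt long, and 206, 255 and 223 longer reads that hold its most-read sequence matched nowhere; from reads of 17 to 30 nt its log2 ratio was -0.67. Of 439 features 51 were lower and 27 higher, and 39 and 34 after median-ratio scaling. Of 6 stress and heat shock genes 3 were higher in dcr1-deltaC33 and 0 lower, with a pooled ratio of 1.63 (1.21 to 2.23, percentile 99.9), while sks2 (0.747, 0.378 to 1.48), ssa2 and hsp90 had intervals that included 1, and ribosomal protein genes had a pooled ratio of 0.928 (0.830 to 1.04).

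Short fragments from transcripts of the silencing pathway itself were near the detection limit. Libraries of RNA cut at 17 to 30 nt do not measure the levels of these mRNAs. The 21 RNAi and heterochromatin factors together had 21, 5 and 12 sense reads in wild type, the deletion and dcr1-deltaC33, the 14 annotated meiotic genes 7, 1 and 5, and the 12 genes next to the centromeres 29, 8 and 15. The Tf2 retrotransposons, 13 near-identical copies, had no single-match read, and act1 (actin), the only cytoskeleton gene measured, had 35, 19 and 32. None of these pooled ratios had an interval that excluded 1, except that of the RNAi and heterochromatin factors in the deletion over wild type from reads of 17 to 30 nt, 0.272 (0.0515 to 0.922), and that of the cytoskeleton genes in dcr1-deltaC33 over wild type after median-ratio scaling, 1.86 (1.18 to 2.92).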

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

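The tests of the tRNA trailers, of general fragments as a source, of each mutant's remainder alone and of depth and composition were chosen after the result was seen.

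Reads that span a splice junction of a tRNA, and so match only the spliced tRNA and not the genome, made up 0.368% of all reads in the dcr1 deletion and 0.446% in dcr1-deltaC33, above the 0.229% of wild type. In the deletion library 8.002% (7.27% to 8.78%) of linker reads carried another library's barcode, against 0.185% in wild type and 0.0565% in dcr1-deltaC33. Each was singled out because it lies in reads outside the comparisons and above the level of wild type.

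Centromeric reads were lost in both mutants. A difference in depth or in rRNA and tRNA fragments would lower other classes alike, but the lowest ratio over wild type among snoRNA, mitochondrial and mRNA sense reads was 0.634, against 0.0139 and 0.0151 for centromeric reads. A mislabelled file would carry another library's barcode, and the lowest share of linker reads with the labelled barcode was 92.0%. That check cannot see RNA exchanged before linkers were added. The loss may thus follow from the dcr1 alleles, a hypothesis that 1 library per strain leaves without a replicate.

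Centromeric reads that stayed in the mutants may come from several sources. Reads carried over from the wild-type library would keep its profile, yet tRNA trailers were 27.2% of them in the deletion (19.3% to 36.3%) and 49.1% in dcr1-deltaC33, against 1.27% in wild type, and without trailers 27.3% (20.8% to 34.6%) of both mutants' reads were 21 to 24 nt with a first U, against 40.5% (39.7% to 41.3%). In the deletion alone that share was 33.7% (23.7% to 44.9%), so carried-over reads and other sources cannot be told apart there: the interval includes wild type, and barcodes set no limit, since the deletion's barcode among wild-type linker reads would bring 24.7 (17.8 to 33.6) reads and the wild-type barcode among the deletion's linker reads 242.5 (219.1 to 267.6), against 83 seen (3.02 and 4.23 against 89 in dcr1-deltaC33). General RNA fragments as the only source would resemble reads of the intergenic or lncRNA class. Reads per kb were no denser (0.492 and 0.527, against 0.953 and 1.41 in that class), though its single-match reads alone gave 0.442 and 0.626. At 17 to 30 nt, however, 33.8% (26.0% to 42.3%) of both mutants' reads were 21 to 24 nt with a first U, and 40.6% (28.9% to 53.1%) in the deletion, against 19.97% in that class. In dcr1-deltaC33 alone this share was 27.1% (17.2% to 39.1%), against 17.0% (15.6% to 18.4%) in the intergenic or lncRNA class, so general fragments stay open there, and a mixture and residual Dicer activity were not tested.

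Fragments of nuclear mRNA were fewer in both mutants. Dicer products of mRNA in wild type are not a likely source, since among reads of 17 to 30 nt those that were not 21 to 24 nt with a first U showed at least 102.7% of the log2 change of the whole class. A rise of tRNA and rRNA fragments in the denominator, as the only cause, would lower all other classes alike. Scaled to mitochondrial reads, the mRNA ratios were 0.665 (0.612 to 0.723) and 0.617 (0.574 to 0.664). That scaling takes mitochondrial reads as otherwise unchanged, which was not tested. Over wild type they were at 0.953 and 1.04, and snoRNA reads at 0.861 (0.750 to 0.987) and 0.905 (0.802 to 1.02). The denominator alone would thus not give the mRNA ratios unless both these classes rose for another reason. How much of the fall it gave stays open. RNA breakdown or ligation that differed between the libraries stays open, as does an effect of the dcr1 alleles, and neither was tested.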

How the results depend on the processing

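Settings without tRNA trailers, those with reads of 17 to 30 nt for subtelomeres, classes and features, and those of gene lists were chosen after the data were seen; for the others the settings were fixed before the data were examined. Centromeric reads stayed lower than wild type, with intervals that excluded 1, in both mutants under all 13 alternatives. The cause of the changes below was not tested unless given. Features are limited by depth, and single-match strand values are the main values themselves. With 1 match the reads of tlh1 and tlh2 were 0 in every library.

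The centromeric share, in wild type, the deletion and dcr1-deltaC33, was 3.20%, 0.0512% and 0.0577% of all reads, 38.9%, 1.23% and 1.27% of matched reads outside rRNA and tRNA, and 111%, 2.42% and 2.60% of mRNA sense reads. It was 19.1%, 0.257% and 0.193% from 20 to 24 nt reads, 23.8%, 0.416% and 0.252% of distinct sequences, 5.28%, 0.0454% and 0.110% of sequences read at least 2 times, and 33.002%, 26.4% and 23.6% with the centromeres first in the class order, which adds their tRNA genes. It was 17.3% and 0.104% (wild type and dcr1-deltaC33) from reads that begin with T, 8.96% and 0.119% from sequences that match in centromeres alone, 10.4% (wild type) with 1 mismatch, 10.6% (wild type) from 17 to 30 nt, and 0.0935% and 0.0711% (mutants) without trailers. The ratio of dcr1-deltaC33 over the deletion was 0.606 from distinct sequences, 2.43 from sequences read at least 2 times and 0.894 with the class order changed.

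Reads of 22 to 23 nt were 34.2% (wild type) and 23.2% (dcr1-deltaC33) of distinct sequences, 55.4% and 45.5% of sequences read at least 2 times, 45.3% (wild type) with 1 match and 25.7% (dcr1-deltaC33) without trailers. A first U was found in 60.0% (wild type) and 33.3% (dcr1-deltaC33) of distinct sequences, 76.2% (wild type) and 7.41% (deletion) of sequences read at least 2 times, 63.0%, 18.8% and 7.89% with 1 match, and 55.1% and 44.3% (mutants) without trailers. The forward share was 54.8% (wild type, distinct), 66.7% and 100% (wild type and deletion, read at least 2 times), and 56.4% and 70.6% (wild type and dcr1-deltaC33) without trailers. Subtelomeric reads with 1 match were 6.02-fold and 2.12-fold lower in the deletion and dcr1-deltaC33, with intervals that included 1 on 11 wild-type reads. For dcr1-deltaC33 over the deletion they gave 2.84, distinct sequences 1.28 and 17 to 30 nt reads 1.41, again with intervals that included 1. The snRNA ratio of the deletion turned to 1.64 from 20 to 24 nt reads.

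Features lower and higher in the deletion were 21 and 88 with median-ratio scaling, 197 and 113 with weighted matches, which add multicopy genes, 92 lower without a minimum, 17 lower with a minimum of 100 reads, and 17 lower from distinct sequences. For dcr1-deltaC33 they were 20 and 101 with that scaling, 280 and 98 with weighted matches, 59 and 22 from distinct sequences, 176 lower without a minimum, 29 lower with a minimum of 100 and 63 lower from 17 to 30 nt. Between the mutants they were 108 and 46 with weighted matches, and 15 and 3 higher with a minimum of 100 and from distinct sequences. Median-ratio scaling turned the ratios over wild type of glycolysis genes to 1.12 and 1.004 (deletion, dcr1-deltaC33), and in dcr1-deltaC33 those of ribosomal proteins to 1.002, stable noncoding RNAs to 1.56 and stress genes to 1.33. Of 50 named changes 49 kept their call under that scaling, 45 of 48 from 17 to 30 nt and 38 of 48 from distinct sequences, where SPATRNAPRO.01 turned to 0.034 (log2) between the mutants. The 50 were picked from these data as the largest changes, and some share reads. Most calls could thus hardly change, and these counts do not speak for the features as a whole.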

Other observations

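Ribosomal RNA fragments differed between the libraries by molecule. Fragments of 28S rRNA rose from 3.48% of matched reads in wild type to 7.18% in the deletion and 13.4% in dcr1-deltaC33, ratios of 2.07 (1.99 to 2.14) and 3.85 (3.74 to 3.97). Those of 18S rRNA were 1.18-fold (1.14 to 1.22) and 1.67-fold (1.62 to 1.72) higher, and those of 5S rRNA fell to 0.750 (0.721 to 0.779) and 0.543 (0.522 to 0.564). The 5.8S rRNA kept 18.7%, 18.1% and 18.6% of matched reads, but its fragments differed in length. Of them 22.8%, 21.1% and 44.6% were 21 to 23 nt long in wild type, the deletion and dcr1-deltaC33, and 42.0%, 49.3% and 22.7% were 18 to 20 nt.

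Among tRNA reads, those that began at the 5′ end of the mature tRNA made up 36.8% (36.5% to 37.2%) in wild type, 26.1% (25.8% to 26.5%) in the deletion and 22.2% (21.8% to 22.5%) in dcr1-deltaC33. Reads that reached the CCA end added to mature tRNAs were 0.649%, 0.579% and 0.572% of all reads. Antisense reads of adh1, for alcohol dehydrogenase, numbered 0, 4 and 14.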
